A study of Ogataea parapolymorpha DL-1 with 4 samples.

How the data were processed

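RNA was taken from 4 cultures of Ogataea parapolymorpha DL-1, 1 for each combination of strain (wild type or met4 mutant) and medium (B medium without or with 0.5 mM cysteine), 2 h after the change of medium. Total RNA was extracted with hot phenol and libraries were made with Illumina protocols, per the labels' protocols. The deposited table holds 1 FPKM value per gene and library, which the authors made with TopHat, Cufflinks 2.1.1 and Cuffdiff, per the submitters' processing notes. These notes name the tools without their roles, and the genome build, the annotation release, the strand setting and the Cuffdiff settings are not given in the sources used here. The authors' deposited table also holds a yes or no mark for each gene in each of the 4 pairings of a wild-type with a mutant library, per the file headers at a threshold of 0.05. Whether that threshold applies to an adjusted p-value is not given in the sources used here. Groups were taken from the titles, genotypes and medium labels of the samples, and table columns from the sample descriptions.

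The table has 5448 rows with a name and a position, of which 5372 carry a locus tag of the reference gene table (assembly Hansenula_2), all 5372 with the same chromosome, start and end, and 76 do not. Gene names and products are those of the table, and 905 rows have no product description. The 7 chromosomes are numbered I to VII. Gene length was taken as the span from start to end, introns included, so it can exceed the transcript length behind FPKM. FPKM values keep no record of the number of reads, so the depth of each library and the counting error of each gene are unknown. The values as deposited were not rescaled. A gene was compared when its mean over the 4 libraries was at least 1 FPKM, which 5342 rows met, and differences were taken between values of log2(FPKM + 1). A fold of 2 or more on this scale was counted as a difference. With 1 library per group no test was made and no p-value, standard error or interval is given. A model that adds an effect of strain and one of medium would take the difference of the 2 responses as its error, and it was not fitted.

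The comparisons made were B medium against B medium with cysteine in each strain, the mutant against the wild type in each medium, and the difference of the 2 responses. The 2 medium comparisons share no library, and nor do the 2 strain comparisons. The comparison of the media in the wild type and that of the strains in B medium share the wild-type library in B medium, so a chance high value in that library makes a gene higher in the first and lower in the mutant in the second. For each of 28 gene lists, matched by gene name or product, the median difference was set beside the medians of 10000 random lists of the same size matched on mean expression in 10 bins. These percentiles describe these libraries and are not p-values. The random lists were not matched on gene length, with which the strain comparisons carry a trend. Correlations were taken across genes, which are not independent replicates.

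Genes were named by a rule set before the data were examined. It takes the deleted gene and the marker LEU2, all members of the 4 sulfur lists (sulfate uptake and assimilation, sulfur amino acid synthesis, sulfur scavenging and transport, sulfur regulators), the 12 highest and 12 lowest differences in each comparison among genes with a mean of at least 5 FPKM, and up to 4 members with the largest absolute difference in each other list. Among the 12 highest and lowest, only genes with a described product are named and the number of the others is given. The other lists were glutathione and thiol redox, iron-sulfur cluster assembly, iron and copper uptake, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, aminoacyl-tRNA synthetases, proteasome, chaperones, other amino acid synthesis, methanol metabolism and peroxisome, nitrate and ammonium use, glycolysis, pentose phosphate, tricarboxylic acid and glyoxylate cycles, respiratory chain and ATP synthase, storage carbohydrate, hexose transport, autophagy and vacuolar proteases, histones and DNA replication, ergosterol synthesis, thiamine and biotin, amino acid permeases and multidrug transporters. The reading of zip1 as the counterpart of MET4, its neighbours, the mating-type genes other than HPODL_04024, the genes of the chromosome II cluster, SOD1, SOD2 and the copper list were chosen after their values were seen. The choice of which list members to print from those the rule allows was also made then.

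Alternatives set before the data were examined were pseudocounts of 0.1 and 5 FPKM, no filter, a filter at a mean of 10 FPKM, median-of-ratios, upper-quartile and TPM scaling, and the correlation without the sulfur lists. Added after the data were seen were the removal of the trend with gene length (a running median over 100 genes on each side, ordered by length), genes of at least 600 bases alone, scaling to the total of those genes, the other list medians under all scalings, and named genes under TPM scaling. The computation was tested on simulated libraries made from the mean FPKM of 5342 genes over the 4 libraries, with a noise of 0.2 (SD, log2). Changes were planted in the simulated wild-type library in B medium, only in genes with a mean of at least 5 FPKM, and read in the wild-type comparison of the media. Of the genes given a 1.5-fold, 2-fold, 4-fold or 8-fold change, 8%, 52%, 100% and 100% passed 2-fold, as did 0.0389% of the unchanged genes. That noise was chosen and not measured. It was the same for every gene, with no trend with gene length, so these rates check the computation and do not describe the real comparisons. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.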

Results

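The transcriptome of Ogataea parapolymorpha DL-1, a methylotrophic yeast, was measured by RNA sequencing in 4 libraries, 1 for each combination of 2 strains and 2 media. The strains were a wild type (leu2 carrying LEU2) and a met4 mutant in which LEU2 replaces MET4. Met4 is known from budding yeast as the transcriptional activator of the sulfate assimilation and methionine genes. Cultures were started at an OD600 of 0.1 in rich medium, grown to 0.3 and moved for 2 h to B medium, described as limited in sulfur, or to the same medium with 0.5 mM cysteine. Values were the authors' FPKM (fragments scaled by transcript length and by the mapped fragments of the library) for 5448 annotated genes and other rows. Of these, 5342 had a mean of at least 1 FPKM over the 4 libraries and were compared. Each group held 1 library, so no difference below has a replicate library behind it, no test was made and no error is attached to any value. Sequencing depth is unknown, because FPKM values do not carry it. All differences are differences of log2(FPKM + 1), which understate the change of low genes.

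Median FPKM over the compared genes was 78.0 in the wild type in B medium, 68.5 in the wild type with cysteine, 64.0 in the mutant in B medium and 64.5 in the mutant with cysteine. The sums over all rows were less even, at 3217249, 2314445, 1407393 and 1329361 FPKM in the same order. Genes under 400 bases held 56.2% and 48.2% of these sums in the wild type and 24.5% and 19.4% in the mutant. The median log2 difference of all genes was 0.19 between the media in the wild type, 0.04 between the media in the mutant, -0.27 between mutant and wild type in B medium, -0.10 between mutant and wild type with cysteine, and -0.20 for the mutant's response minus the wild type's. Rescaling each library to the same sum (TPM) shifted these 5 medians by -0.44, -0.08, 1.14, 0.76 and 0.37. Median-of-ratios scaling shifted them by -0.19, -0.05, 0.25, 0.10 and 0.15, upper-quartile scaling by -0.06, 0.05, 0.30, 0.19 and 0.11, and scaling to the total of genes of at least 600 bases, added after the data were seen, by -0.08, 0.10, 0.23, 0.05 and 0.17. Each list shifts by about as much, so a list median of the opposite sign and nearer to 0 than the shift takes the other sign under that scaling, and list medians are to be read against the medians of all genes.

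No row of the table is named MET4, and the row zip1 (HPODL_03459, chromosome IV, 763543 to 764535), described as transcription factor zip1, was taken as its counterpart after the values had been seen. Zip1 is the name of the Met4-like factor of fission yeast. The zip1 row had 485 FPKM in the wild type in B medium, 202 with cysteine, and was listed at 0 in both mutant libraries. The neighbouring row HPODL_05198 (chromosome IV, 764635 to 764962), whose product is uncharacterized, had 2343 and 2757 FPKM in the wild type and was also listed at 0 in both mutant libraries. The rows on either side, HPODL_03458 and HPODL_03460, were present in the mutant with 570.0 and 63.6 FPKM in B medium. LEU2 (HPODL_02130), the marker, had 403 and 396 FPKM in the wild type and 696 and 810.5 in the mutant. The 0 values at this locus fall in the libraries labelled as the mutant. They cover both zip1 and HPODL_05198, so no strain difference below can be assigned to the loss of zip1 alone. The same holds for the differences of responses.

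**Figure D1:**
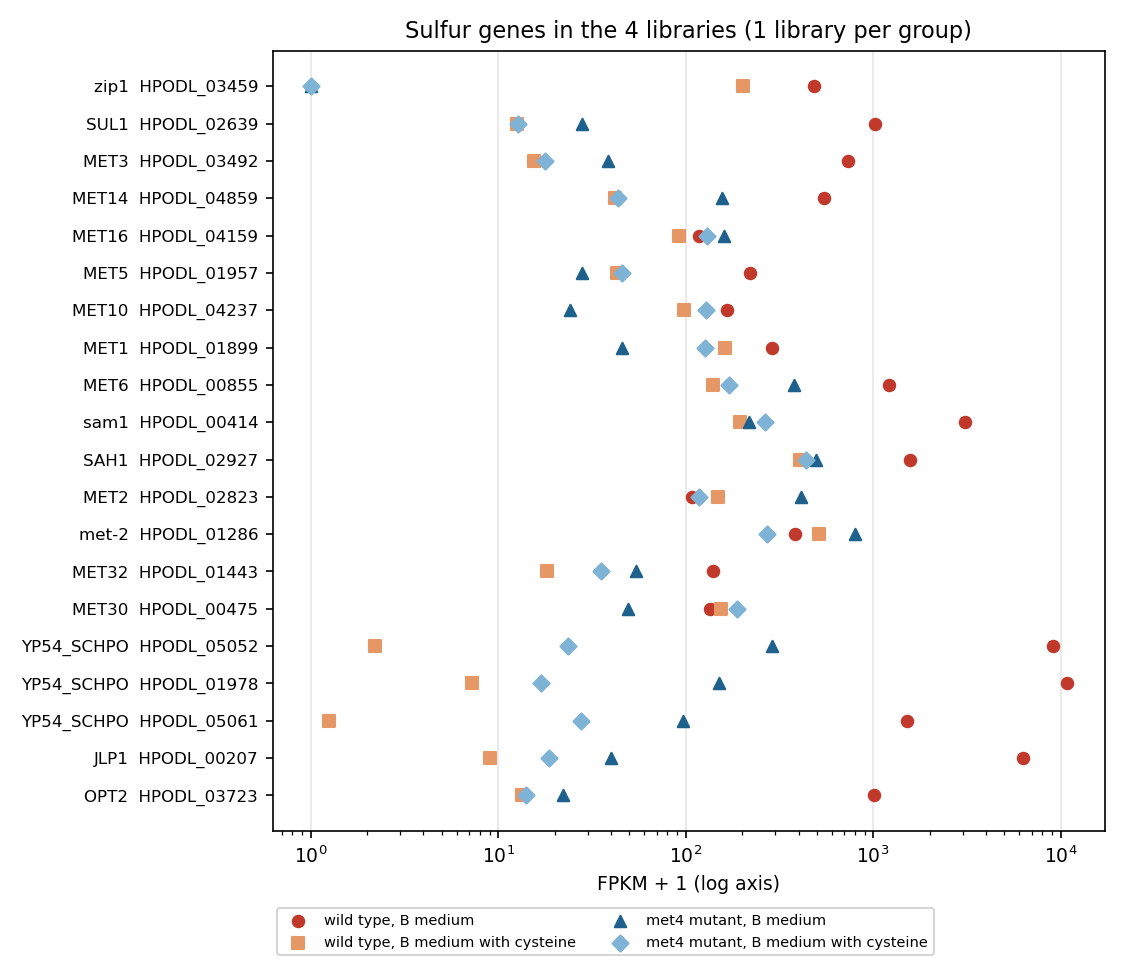
FPKM + 1 (log axis) of zip1 and 19 genes of sulfur metabolism, with 1 point for each of the 4 libraries. The wild type in B medium lies far to the right for SUL1, MET3 and the sulfonate dioxygenases (HPODL_05052 at 9095 FPKM), the mutant in B medium lies between it and both libraries with cysteine for these genes (286 FPKM), and both mutant points of zip1 lie on top of each other at 0 FPKM.

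The comparison of the media in the wild type asks how cells differ between B medium and the same medium with cysteine. The largest positive differences in described genes were led by genes for the use of organic sulfur. A sulfonate dioxygenase row, HPODL_05052, had 9095 FPKM in B medium and 1.21 with cysteine, a log2 difference of 12.01. JLP1 (HPODL_00207), the enzyme that frees sulfite from sulfonates in budding yeast, had 6263 and 8.01 FPKM (9.44). The sulfate permease SUL1 (HPODL_02639) had 1017 and 11.6 FPKM (6.33), and MET3 (HPODL_03492), which activates sulfate, had 738 and 14.5 FPKM (5.58). Cytosolic ribosomal protein genes were higher in B medium (list median 2.65), while mitochondrial ribosomal protein genes (-1.12) and iron and copper uptake genes (-1.03) were lower.

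Over all genes, 1259 were at least 2-fold higher and 692 at least 2-fold lower in B medium than with cysteine. That is 64.5% higher, against 753 higher and 1125 lower (40.1% higher) with TPM scaling. Among the 12 genes with the largest positive differences, the described ones were 2 further rows of the same sulfonate dioxygenase family, HPODL_01978 (10802 and 6.23 FPKM) and HPODL_05061 (1517 and 0.254 FPKM), liz1 (HPODL_05053, named for a pantothenate transporter, 1077 and 0.673 FPKM), FMO GS-OX1 (HPODL_05054, a flavin-containing monooxygenase, 547 FPKM and listed at 0 with cysteine) and an aryl-alcohol dehydrogenase (HPODL_01099, 1543 and 2.64 FPKM), besides HPODL_05052 and JLP1. The other 5 had no described product. Rows that share a name (these dioxygenases, OPT2, PRX1, DIP5, the histones and the cytosolic ribosomal protein pairs) can share reads, so their single values are uncertain. At the other end stood GPR1 (HPODL_00537, 44.1 and 8008 FPKM), the copper transporter CTR1 (HPODL_01154, 139 and 12774 FPKM), the metalloreductase FRE7 (HPODL_04299, 33.6 and 2974 FPKM), a second aryl-alcohol dehydrogenase (HPODL_00007, 23.6 and 1752 FPKM) and an alcohol dehydrogenase (adh, HPODL_04528, 183 and 7515 FPKM), with 7 rows lacking a described product.

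Of the 10 genes of sulfate uptake and assimilation, 4 were at least 2-fold higher in wild-type B medium and 0 at least 2-fold lower. These were SUL1, MET3, MET14 (HPODL_04859, 548 and 41.1 FPKM, 3.70) and MET5 (HPODL_01957, a sulfite reductase subunit, 218 and 42.3 FPKM, 2.34). The list's median difference was 0.82 (interquartile range 0.73 to 3.36), at percentile 97.4 of 10000 random lists matched on expression. Smaller differences were found for MET1 (0.84), met8 (0.80), MET10 (0.77), HAL21 (0.72) and MET16 (0.35), and a second sulfate transporter row, LPZ3C (HPODL_04102), stood at -0.96.

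Genes of sulfur amino acid synthesis differed in direction, with 4 of 13 at least 2-fold higher, 2 at least 2-fold lower and a median of -0.03 (percentile 38.2). The S-adenosylmethionine synthase sam1 (HPODL_00414) had 3086 and 193 FPKM (3.99), the methionine synthase MET6 (HPODL_00855) 1210.2 and 139 (3.11), SAH1 (HPODL_02927) 1579.9 and 404 (1.97) and MET13 (HPODL_02993) 106 and 26.7 (1.95). The cysteine synthase row HPODL_05065 (-1.33) and mmuM (-1.09) were the low ones. The remaining differences were 0.63 for the cysteine synthase row HPODL_02013, 0.70 for MET12, -0.03 for MET7, -0.06 for the cystathionine gamma-synthase row HPODL_01631, -0.42 for the cystathionine beta-lyase met-2, -0.45 for MET2 and -0.64 for OAS-TL.

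In the scavenging and transport list, 10 of 21 genes were at least 2-fold higher and 3 at least 2-fold lower (median 0.94, percentile 99.1). Beyond the dioxygenases and JLP1, these were the oligopeptide transporter OPT2 at HPODL_03723 (1009 and 12.5 FPKM, 6.23), the gamma-glutamyltransferase ywrD (3.35), a dipeptidase (HPODL_04549, 2.84), the arylsulfatase atsA (2.13), a cystinosin homolog (HPODL_03115, 1.03) and a further OPT2 row (HPODL_00610, 9.48 FPKM with cysteine and just past 2-fold higher in B medium). The lower ones were the OPT2 row HPODL_00173 (23.7 and 208 FPKM, -3.08), a second JLP1 row with low values (HPODL_00875, 0.0550 and 6.43 FPKM) and a dipeptidase (HPODL_01032, -1.80). MUP3 (0.94), the cystinosin homolog HPODL_02012 (0.66), DUG1 (-0.15), ALKBH3 (-0.25), DUG2 (-0.40), ECM38 (-0.49), DUG3 (-0.68) and the oligopeptide transporter row HPODL_01579 (-0.94) stayed within 2-fold. Among the 5 regulators (median -0.33, percentile 25.8), MET32, a DNA-binding partner of Met4 in budding yeast, had 139 and 17.2 FPKM (2.94). MET30, the F-box protein that restrains Met4 there, had 133 and 153 (-0.20), SKP1 stood at -0.33 and the CDC34 rows at -0.82 and -1.03.

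Outside sulfur metabolism, 76 of 78 cytosolic ribosomal protein genes were at least 2-fold higher in wild-type B medium (median 2.65, interquartile range 2.15 to 3.11, above all 10000 random lists). RPS22A at HPODL_01192 had 4645 and 114 FPKM and RPL22A 4517 and 151. Respiratory chain and ATP synthase genes had a median of 1.64 (41 of 59 higher, 9 lower), with CIB22 of complex I at 1684 and 78.7 FPKM and the cytochrome oxidase assembly factor COX15 at 119 and 1607. Histone and DNA replication genes had a median of 1.12 (30 of 53 higher, 1 lower), led by histone H3 (HHT2, 22049 and 259.8 FPKM) and H4 (HHF3, 45754 and 1109.7 FPKM), and the tricarboxylic acid and glyoxylate cycle list one of 0.98 (15 of 32 higher, 2 lower), among them SDH4 (1859 and 189 FPKM). Each of these 4 lists lay at or above percentile 99.8. The replication list also holds YHM2 (HPODL_03472, 341 and 11.2 FPKM), a mitochondrial carrier that is neither a histone nor a replication protein. Amino acid permeases had a median of 0.89 (13 of 29 higher, 5 lower, percentile 99.8), led by 2 DIP5 rows (HPODL_00008, 179 and 1.18 FPKM, and HPODL_03243, 307 and 3.35 FPKM).

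Mitochondrial ribosomal protein genes lay lower in B medium, with 42 of 69 at least 2-fold lower and a median of -1.12, below all 10000 random lists. Iron and copper uptake genes had a median of -1.03 (8 of 16 lower, 2 higher), and only 1 random list had a lower one. Glycolysis and gluconeogenesis genes had a median of -0.63 (14 of 34 lower, 8 higher, percentile 0.140). That list holds the aryl-alcohol dehydrogenases named above, which are not glycolytic enzymes. In the glutathione and thiol redox list (median 0.34, 9 of 32 higher and 8 lower), the peroxiredoxin PRX1 at HPODL_03023 had 3015 and 46.5 FPKM, PRX1 at HPODL_02878 18571 and 857, GRX8 5037 and 291 and the thioredoxin reductase trxB 47.4 and 1389. The nitrate and ammonium list had a median of only 0.30 but 10 of 28 higher, among them niiA, crnA and YNR1 of nitrate use (212 and 1.69, 879 and 10.4 and 109 and 1.38 FPKM) and the ammonium transporter MEP2 (2835 and 155 FPKM). With TPM scaling the medians of the redox and the nitrate list were -0.11 and -0.09. Aminoacyl-tRNA synthetases had a median of -0.25, and its 4 largest differences were all in enzymes of mitochondria, led by MSW1 (37.4 and 529 FPKM) and MST1 (24.7 and 209 FPKM). The other lists had medians between -0.34 and 0.80. They were, with percentiles among the random lists in brackets, -0.34 (6.08) for the proteasome, -0.23 (0.89) for methanol metabolism and peroxisome, -0.13 (7.355) for autophagy and vacuolar proteases, -0.08 (29.59) for storage carbohydrate, -0.06 (22.76) for chaperones. They were -0.05 (41.46) for iron-sulfur cluster assembly, -0.0022 (34.93) for the synthesis of other amino acids, 0.14 (30.5) for ribosome biogenesis, 0.24 (61.36) for the pentose phosphate pathway, 0.25 (59.09) for multidrug transporters (-0.21 with TPM scaling), 0.51 (90.65) for ergosterol synthesis, 0.62 (79.48) for hexose transport and 0.80 (89.52) for thiamine and biotin.

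The same comparison in the met4 mutant asks how cells without the zip1 locus respond. BUL1 (HPODL_03171), a ubiquitin ligase adaptor, had 598 FPKM in B medium and 16.2 with cysteine (5.12), and pyroA (HPODL_04092), of pyridoxine synthesis, had 1694 and 117 (3.84). CTR1 had 169 and 16794 FPKM (-6.63), close to its wild-type difference of -6.52. SUL1 had 27.1 and 11.8 FPKM and JLP1 38.8 and 17.8, differences of 1.13 and 1.09.

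In the mutant 709 genes were at least 2-fold higher and 649 at least 2-fold lower in B medium (52.2% higher). Other scalings turned or widened this balance. The counts were 657 and 703 with median-of-ratios, 619 and 715 with TPM, 773 and 610 with upper-quartile scaling and 821 and 573 with scaling to genes of at least 600 bases. The described genes among the 12 largest positive differences were, besides that BUL1 row and pyroA, a second BUL1 row (HPODL_02275, 1739 and 117 FPKM), the asparaginyl-tRNA synthetase DED81 (1299 and 72.3 FPKM), the sugar transporter row STL1 (HPODL_04500, 506 and 31.2 FPKM), SDH4 (1626 and 104 FPKM), LYS4 of lysine synthesis (324 and 23.1 FPKM) and the aconitase ACO1 (1605 and 118 FPKM), with 4 rows lacking a described product. At the low end, besides CTR1, were FRE7 (70.5 and 4239 FPKM), trxB (112 and 2950.2), YEA4 (93.2 and 1822), SLM3 of mitochondrial tRNA modification (9.19 and 174), MDM35 (39.3 and 645), PUF3, an RNA-binding protein of mitochondrial messages in budding yeast (73.0 and 1027), COX15 (132 and 1797), SCO1 (119.8 and 1557), MRPL33 (76.8 and 914) and the zinc transporter ZRT2 (182 and 2118), with 1 row lacking a described product.

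The sulfate assimilation list had a median of 0.26 in the mutant (percentile 83.1), with 4 genes at least 2-fold higher (SUL1, MET3 at 1.11, MET14 at 1.85 and met8 at 1.46) and 3 at least 2-fold lower (MET10 at -2.41, MET1 at -1.47 and LPZ3C at -1.13). Sulfur amino acid synthesis had a median of -0.01 (3 higher, 3 lower of 13). MET2 and met-2, of homocysteine supply, were among the higher ones at 1.80 and 1.56, with MET6 at 1.15, while sam1 stood at -0.27. Scavenging genes had a median of 0.15 (4 of 21 higher, 2 lower), with HPODL_05052 at 3.61 and OPT2 HPODL_03723 at 0.67. The regulators had a median of -0.39, and MET30 stood at -1.93.

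Other amino acid synthesis stood out in the mutant, with 27 of 50 genes at least 2-fold higher, 1 at least 2-fold lower and a median of 1.14, above all 10000 random lists. LEU4 had 862 and 105 FPKM and ILV3 344 and 44.3. The tricarboxylic acid list holds LYS4 and LYS21 too, which belong to lysine synthesis. Cytosolic ribosomal proteins (median 1.69, 70 of 78 higher, 0 lower) and the tricarboxylic acid list (1.32, 18 of 32 higher, 1 lower) were also above all random lists, and mitochondrial ribosomal proteins (-1.92, 66 of 69 lower, 0 higher) below all. Respiratory genes had a median of 0.52 (9 higher and 9 lower of 59) and histone and replication genes 0.13 (7 of 53 higher, 3 lower), against 1.64 and 1.12 in the wild type. The remaining medians, with percentiles in brackets, were 0.59 (98.07) for hexose transport, 0.50 (97.61) for the proteasome, 0.33 (99.83) for ribosome biogenesis, 0.30 (91.85) for autophagy, 0.25 (75.19) for iron-sulfur assembly, 0.18 (85.17) for aminoacyl-tRNA synthetases, 0.01 (33.26) for thiol redox. Negative ones were -0.02 (36.92) for chaperones, -0.16 (26.05) for storage carbohydrate, -0.17 (23.38) for ergosterol, -0.18 (8.76) for nitrate and ammonium, -0.19 (24.69) for multidrug transporters, -0.21 (16.86) for thiamine and biotin, -0.22 (6.46) for amino acid permeases, -0.27 (14.53) for pentose phosphate, -0.30 (2.55) for glycolysis, -0.35 (4.17) for iron and copper uptake and -0.45 (0.09) for methanol metabolism and peroxisome.

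**Figure D2:**
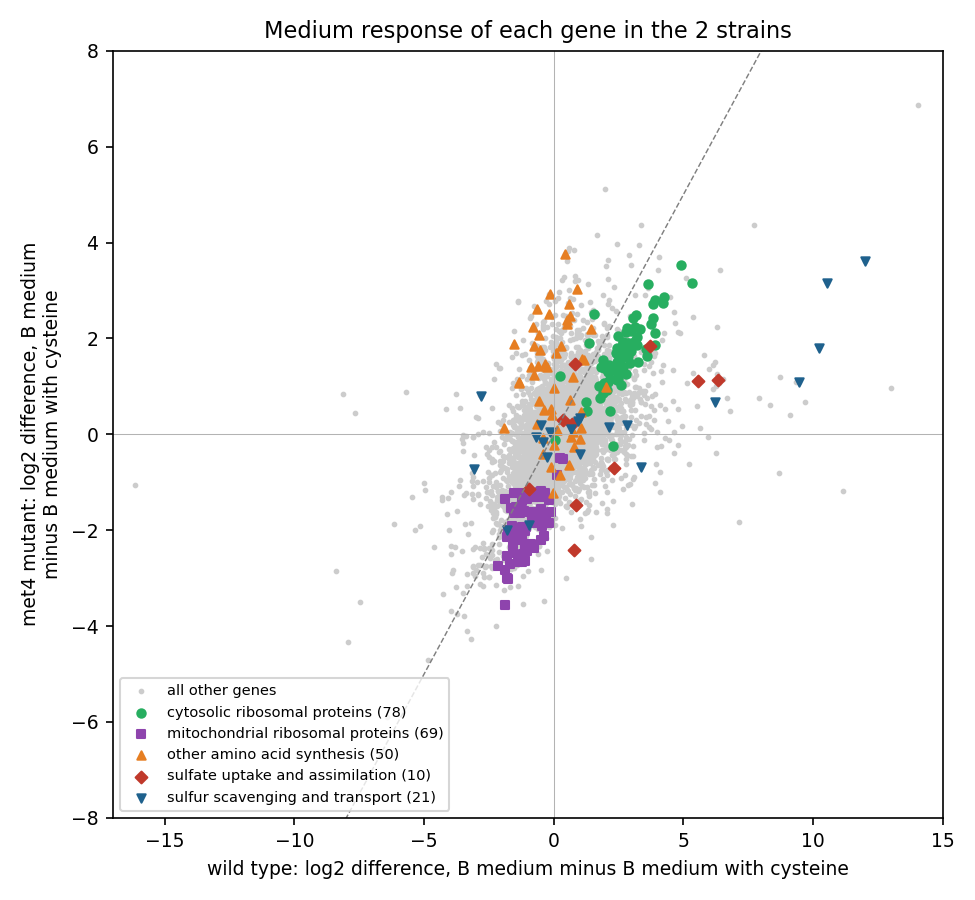
Log2 difference between the media in the wild type (x axis) and in the met4 mutant (y axis), 1 point per gene with a mean of at least 1 FPKM, with 5 gene lists coloured, axes of different scales and a dashed line of equal differences. Scavenging and assimilation genes reach 12.01 in the wild type and at most 3.61 in the mutant, while other amino acid synthesis lies higher in the mutant (median 1.14).

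Set side by side, the 2 responses share no library. Of the 42 genes at least 32-fold higher in wild-type B medium, 25 were at least 2-fold higher in mutant B medium and 1 at least 32-fold. Their median difference was 6.35 in the wild type and 1.09 in the mutant. These genes were chosen for their wild-type values, which favours larger wild-type differences by chance alone. Of the 1259 genes at least 2-fold higher in the wild type and 709 in the mutant, 355 were shared, where independent lists would share 167. On the lower side 366 were shared of 692 and 649, against 84.1 for independent lists. Across the 5342 genes, which are not independent replicates, the 2 responses correlated with a Pearson r of 0.502 and a Spearman rho of 0.472.

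The mutant's response minus the wild type's asks which responses depend on the zip1 locus, and 3 of the 12 genes with the lowest values were sulfonate dioxygenase rows. These rows, HPODL_05061, HPODL_05052 and JLP1, had differences of responses of -8.45, -8.40 and -8.35, and a clavaminate synthase-like row (HPODL_01980) one of -8.97. Others of the 12 lowest were liz1 (-8.24), the transporter row SEO1 (HPODL_05071, -7.72), HPODL_01099 (-7.54) and FMO GS-OX1, whose wild-type value with cysteine is listed at 0, with 4 rows lacking a described product. AIFM2 (4.59) and HPODL_00007 (4.29) were the described genes among the 12 highest, beside 10 others. In the assimilation list the difference of responses was negative by at least 2-fold in 6 of 10 genes and positive in 0. The list median was -2.08, below all 10000 random lists, with SUL1 at -5.20, MET3 at -4.47, MET10 at -3.17 and MET5 at -3.05. The sign does not tell which strain responded more strongly. Mitochondrial ribosomal proteins, for example, have a negative value with medians of -1.12 in the wild type and -1.92 in the mutant.

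Scavenging genes had a median difference of responses of -0.67 (9 of 21 negative by at least 2-fold, 2 positive). That of sulfur amino acid synthesis was -0.14 (5 negative, 2 positive), with sam1 at -4.27 and MET2 at 2.25, and that of the regulators -0.07. With TPM scaling the median of sulfur amino acid synthesis was 0.23, and that of the regulators 0.33. Nitrate genes had a median of -0.57 (12 of 28 negative, 6 positive), with crnA at -6.65 and MEP2 at -3.10. With percentiles in brackets, histone and replication genes stood at -1.26 (below all), cytosolic ribosomal proteins at -1.02 (below all), ergosterol synthesis at -1.05 (higher than 25 of the random lists), respiratory genes at -0.92 (0.015), mitochondrial ribosomal proteins at -0.90 (below all) and amino acid permeases at -0.77 (0.94). The remaining lists had medians, with percentiles in brackets, of -0.92 (5.34) for thiamine and biotin, -0.71 (9.85) for hexose transport, -0.21 (56.59) for glycolysis, -0.21 (46.16) for pentose phosphate, -0.17 (46.06) for storage carbohydrate, -0.17 (54.57) for methanol metabolism and peroxisome, -0.02 (74.53) for chaperones. Positive ones were 0.07 (85.97) for the tricarboxylic acid list, 0.09 (86.75) for aminoacyl-tRNA synthetases, 0.13 (94.14) for thiol redox, 0.26 (87.17) for multidrug transporters, 0.28 (above all) for ribosome biogenesis, 0.57 (99.63) for iron and copper uptake, 0.59 (99.96) for autophagy and 0.70 (97.22) for iron-sulfur assembly. Other amino acid synthesis stood at 1.09 (25 of 50 positive, 6 negative), with LYS21 at 3.42 and ASN1 at 3.27. The proteasome stood at 0.85 (10 of 30 positive, 0 negative). In all, the difference of responses was positive by at least 2-fold in 599 genes and negative by at least 2-fold in 1186 (33.6% positive). With TPM scaling the counts were 996 and 671 (59.7%), and with scaling to the total of genes of at least 600 bases 770 and 935 (45.2%).

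Comparing the strains in B medium asks how the mutant differs under sulfur limitation, and it shares the wild-type library in B medium with the comparison of the media in the wild type. The median of the sulfate assimilation list was lower in the mutant as deposited (-2.24) and under the 4 scalings tried (the nearest to 0 being -1.04 with TPM), although MET16 (0.43) and met8 (0.22) were higher in the mutant. SUL1 had 27.1 FPKM against 1017 in the wild type (-5.18), MET3 37.4 against 738 (-4.26), JLP1 at HPODL_00207 38.8 against 6263 (-7.30) and sam1 218 against 3086 (-3.82). The second JLP1 row (HPODL_00875) had 13.0 against 0.0550 (3.73). Genes for the synthesis of other amino acids differed in direction, with 22 of 50 at least 2-fold higher and 10 at least 2-fold lower, LYS21 among the higher at 4203 against 826 FPKM (2.35). The cell wall protein gene RHD3 (HPODL_01648) had 1709.5 against 43.5 (5.26).

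Besides zip1 and JLP1, the described genes among the 12 lowest were HPODL_01978 (149.9 and 10802 FPKM in mutant and wild type), SEO1 HPODL_05071 (11.5 and 836), dad4 (19.3 and 1772) and HPODL_05304, a UPF0495 family member (3762 and 244039), the last 2 under 400 bases long. A further 6 had no described product. Among the 12 highest were RHD3, a hydroxy-oxoglutarate aldolase (HPODL_05174, 68.2 and 1.23 FPKM) and the mating-type gene MATA1 at HPODL_04024, listed at 0 in the wild type and at 36.97 FPKM in the mutant, with 9 rows lacking a described product. In the assimilation list 7 of 10 genes were at least 2-fold lower and 0 at least 2-fold higher (median -2.24, interquartile range -2.93 to -0.42, below all 10000 random lists), including MET5 (-2.97), MET10 (-2.79), MET1 (-2.66), MET14 (-1.81) and HAL21 (-1.27). Sulfur amino acid synthesis had 6 of 13 lower and 2 higher (median 0.16), the higher ones being MET2 (1.92) and met-2 (1.06). Scavenging had 7 of 21 lower and 2 higher (median -0.37, 0.71 with TPM scaling), and of the regulators MET30 stood at -1.45 and MET32 at -1.36 (list median -0.81, 0.38 with TPM scaling and -0.21 with the trend with gene length removed). The median of all genes in this comparison was 0.87 with TPM scaling.

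The median of other amino acid synthesis was 0.82, above all random lists, although 10 genes of the list were at least 2-fold lower. THR4 had 1877 and 426 FPKM in mutant and wild type. Iron and copper uptake (0.90, 7 of 16 higher, 1 lower), iron-sulfur cluster assembly (0.85, 4 of 9 higher, 1 lower), autophagy and vacuolar proteases (0.66, 5 of 29 higher, 5 lower) and the proteasome (0.51, 5 of 30 higher, 0 lower) had medians that all lay at or above percentile 99.6. SIT1, a siderophore transporter, had 97.7 and 8.06 FPKM and NAR1, of cytosolic iron-sulfur assembly, 67.3 and 21.6. Histone and replication genes lay lower (-1.76, 39 of 53 at least 2-fold lower, 1 higher, below all random lists), with MCM7 at 8.45 and 89.7 FPKM, as did cytosolic ribosomal proteins (-1.53, 60 of 78), mitochondrial ribosomal proteins (-1.41, 49 of 69) and respiratory genes (-1.28, 41 of 59). Median gene length was 1146 bases for the histone and replication list. It was 523, 678 and 528 bases for the cytosolic ribosomal, mitochondrial ribosomal and respiratory lists, which are shorter. With the trend with gene length removed the medians of these lists, in the order above, were -1.43, -0.79, -0.95 and -0.78. Then 35, 26, 30 and 27 of their genes were at least 2-fold lower. The other medians, with percentiles in brackets, were -0.64 (9.47) for ergosterol synthesis (0.50 with TPM scaling), -0.48 (33.55) for thiamine and biotin (0.68 with TPM scaling), -0.27 (48.62) for amino acid permeases (0.77 with TPM and 0.02 with upper-quartile scaling), -0.23 (49.84) for aminoacyl-tRNA synthetases, -0.19 (52.45) for storage carbohydrate, -0.11 (76.05) for nitrate and ammonium, where crnA (37.5 and 879 FPKM) and MEP2 (187 and 2835 FPKM) were among the lowest, -0.10 (82.84) for methanol metabolism and peroxisome, -0.09 (80.93) for the tricarboxylic acid list, -0.02 (91.98) for thiol redox, -0.02 (73.25) for pentose phosphate, -0.0039 (98.28) for ribosome biogenesis, 0.20 (98.56) for chaperones, 0.23 (87.75) for multidrug transporters, 0.26 (99.32) for glycolysis and 0.27 (97.22) for hexose transport. Some percentiles moved with the length trend removed, to 2.27 for ergosterol synthesis, 90.88 for chaperones and 99.93 for hexose transport.

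In total 562 genes were at least 2-fold higher and 1332 at least 2-fold lower in the mutant in B medium (29.7% higher). The split depended on the scaling, at 795 and 1002 (44.2%) with median-of-ratios, 853 and 951 (47.3%) with upper-quartile, 765 and 1027 (42.7%) with scaling to genes of at least 600 bases, and 2369 and 336 (87.6%) with TPM. With the trend with gene length removed it was 692 and 981 (41.4%).

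**Figure D3:**
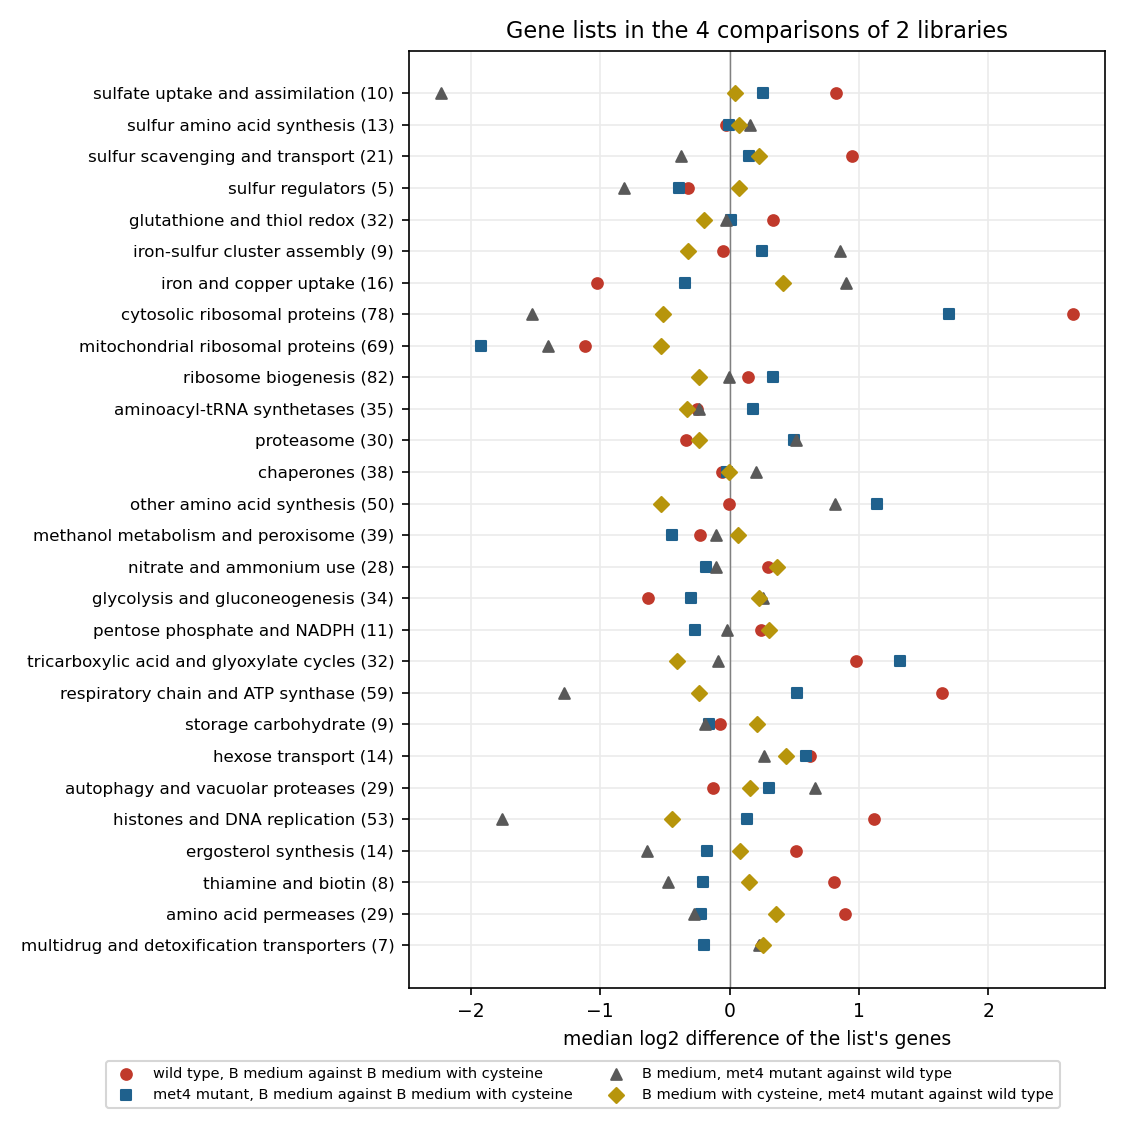
Median log2 difference of the genes of each of 28 lists (number of genes in brackets) in the 4 comparisons of 2 libraries. Sulfate uptake and assimilation is the lowest list in B medium between the strains (-2.24) and close to 0 with cysteine (0.04, 0.80 with TPM scaling against 0.66 for all genes), and cytosolic ribosomal proteins are the highest in wild-type B medium (2.65).

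Comparing the strains with cysteine supplied asks how the mutant differs when organic sulfur is present. Sulfate assimilation genes were nearly level as listed (median 0.04). With TPM scaling their median was 0.80, where that of all genes was 0.66. SUL1 had 11.8 FPKM in the mutant and 11.6 in the wild type (0.02), MET3 16.8 and 14.5 (0.21) and MET14 42.6 and 41.1 (0.05). No gene of the assimilation list differed 2-fold (0 higher, 0 lower, as listed). The sulfonate dioxygenase rows, very low in the wild type with cysteine, were higher in the mutant, as HPODL_05061 at 26.8 and 0.254 FPKM (4.47) and HPODL_05052 at 22.5 and 1.21 (3.41). RHD3 again differed, with 2247 and 28.6 FPKM (6.25).

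The mutant with cysteine had 366 genes at least 2-fold higher and 396 at least 2-fold lower (48.0% higher). The split was 429 and 325 (56.9%) with median-of-ratios scaling, 394 and 358 (52.4%) with scaling to genes of at least 600 bases, 502 and 267 (65.3%) with upper-quartile scaling, 1478 and 118 (92.6%) with TPM, 414 and 216 (65.7%) with the length trend removed and 328 and 151 (68.5%) among genes of at least 600 bases. Described genes among the 12 highest were RHD3, IME4 (HPODL_02439, an RNA methyltransferase of meiosis, 950.1 and 19.1 FPKM), MATA1 at HPODL_04024 (38.4 FPKM and listed at 0 in the wild type) and HPODL_05061, beside 8 others. At the low end were zip1, TAR1 (HPODL_05380, a gene that lies in the ribosomal RNA repeat in budding yeast, so its reads are uncertain, 491 and 14923 FPKM) and HPODL_05304 (2843 and 81814 FPKM), beside 9 others.

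Sulfur scavenging had 7 of 21 genes at least 2-fold higher in the mutant with cysteine and 1 at least 2-fold lower (median 0.23, percentile 98.2, or 90.05 with the length trend removed). Sulfur amino acid synthesis had a median of 0.07 with 1 gene lower (cysteine synthase HPODL_02013, -1.13), and the regulators 0.07. The low end of the libraries was not level. Among genes of at least 600 bases, 177 lay below 5 FPKM in the wild type with cysteine and 105 in the mutant with cysteine, against 90 and 70 in B medium. The median of other amino acid synthesis was lower in the mutant here (-0.53, percentile 0.0600, 11 of 50 genes at least 2-fold lower, 1 higher) but 0.26 with TPM scaling (0.66 for all genes), with ILV3 at 44.3 and 342 FPKM. So were those of mitochondrial ribosomal proteins (-0.53, below all random lists, 0.26 with TPM scaling), histones and replication (-0.45, percentile 0.0100, 0.32 with TPM scaling), ribosome biogenesis (-0.24, percentile 1.52, 4 of 82 lower, 0.52 with TPM scaling) and aminoacyl-tRNA synthetases (-0.33, percentile 3.04, 0.46 with TPM scaling). Negative medians nearer to the middle of the random lists as deposited were those of the tricarboxylic acid list (-0.40, percentile 7.24, 5 higher and 5 lower, 0.39 with TPM scaling), cytosolic ribosomal proteins (-0.51, percentile 10.9, -0.19 with the length trend removed, 0.28 with TPM scaling) and iron-sulfur assembly (-0.32, percentile 26.9, 1 of 9 lower, 0.47 with TPM scaling). With the length trend removed the tricarboxylic acid list lay at percentile 1.99, beside ribosome biogenesis at 1.95.

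Medians higher in the mutant with cysteine were those of hexose transport (0.44), iron and copper uptake (0.41), nitrate and ammonium use (0.37, 9 of 28 at least 2-fold higher, 0 lower), amino acid permeases (0.36), the pentose phosphate pathway (0.30) and glycolysis (0.22), all at or above percentile 98.5. With the length trend removed the pentose phosphate pathway lay at percentile 96.025 and the others at or above 98.22. The nitrate transporter crnA had 49.1 and 10.4 FPKM. The remaining medians, with percentiles in brackets, were 0.26 (89.73) for multidrug transporters, 0.21 (93.41) for storage carbohydrate, 0.16 (97.58) for autophagy, 0.15 (86.42) for thiamine and biotin, 0.08 (86.95) for ergosterol, 0.07 (93.22) for methanol metabolism and peroxisome, -0.0048 (89.15) for chaperones, -0.20 (62.94) for thiol redox, -0.24 (61.26) for respiratory genes and -0.24 (56.73) for the proteasome. Autophagy lay at percentile 82.85 with the length trend removed. Across all genes the strain differences in the 2 media, which share no library, correlated with a Pearson r of 0.348 and a Spearman rho of 0.280, and with 0.201 and 0.180 over the 4547 genes of at least 600 bases.

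Both strain comparisons carried a trend with gene length, taken as the span from start to end with any introns. Genes under 400 bases had a median difference of -2.00 in B medium and -1.31 with cysteine (274 genes, 201 and 153 of them at least 2-fold lower in the mutant). QCR9, a short subunit of respiratory complex III, had 1675 and 37237 FPKM in mutant and wild type in B medium. The class of 1501 to 2500 bases had medians of -0.05 and -0.01. Between the media the short genes had medians of 0.52 in the wild type and 0.01 in the mutant.

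**Figure D4:**
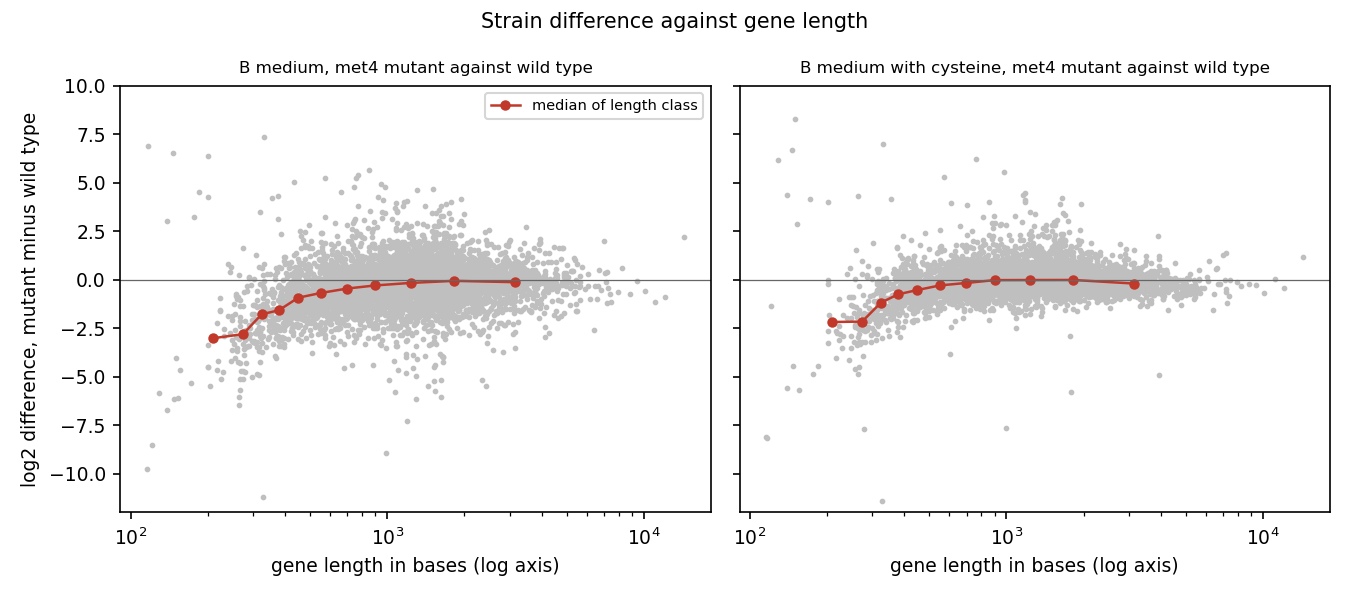
Log2 difference between the mutant and the wild type (y axis) against gene length in bases (log axis), in B medium (left) and with cysteine (right), 1 grey point per gene. The red line joins the medians of 11 length classes, which reach -3.01 and -2.17 in genes of up to 250 bases and are -0.05 and -0.01 at 1501 to 2500 bases.

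The authors' deposited table marks, at a threshold it writes as 0.05, 13 rows as different between wild type and mutant in B medium and 57 with cysteine. In the authors' deposited table, 10 of the 13 and 35 of the 57 are under 400 bases, a class that holds 6.88% of the rows. In all 4 pairings of a wild-type with a mutant library the authors' deposited table marks 3 rows, namely zip1, its neighbour HPODL_05198 and MATA1 at HPODL_04024.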

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

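All tests in this part were chosen after the results were seen. Of 355 named genes and lists examined, 8 genes stood out because the 2 strains differed between the media in opposite directions, each by at least 2-fold. The 2-fold limit was also set after the values were seen, since at 1.5-fold 31 genes met it. Under the scalings, applied to this count after the data were seen, fewer of the 8 met it, with 7 under median-of-ratios and under upper-quartile scaling (without HPODL_04365), 6 with TPM (without HPODL_04365 and RKI1) and 6 both with scaling to genes of at least 600 bases and with the length trend removed (without HPODL_04365 and INP1). None of these differences was tested, because each rests on 1 library per group. A clavaminate synthase-like row (HPODL_01980) differed by 7.14 in the wild type and -1.83 in the mutant, a difference of -8.97. GRX8 (HPODL_00292), a glutaredoxin, differed by 4.11 in the wild type and -1.20 in the mutant, a difference of -5.31. The small heat shock protein gene HSP26 (HPODL_03869) differed by 2.06 in the wild type and -1.64 in the mutant, a difference of -3.71. YG64_SCHPO (HPODL_04365), of the amino acid permease list, differed by 1.05 in the wild type and -1.91 in the mutant, a difference of -2.96. RKI1 (HPODL_02541), a pentose phosphate isomerase with a second row of the same name, differed by 1.35 in the wild type and -1.29 in the mutant, a difference of -2.63. INP1 (HPODL_01512), of peroxisome inheritance, differed by 1.56 in the wild type and -1.06 in the mutant, a difference of -2.62. The other 2 were higher in the mutant's B medium. LYS21 (HPODL_02806), the first enzyme of lysine synthesis, differed by -1.55 in the wild type and 1.88 in the mutant, a difference of 3.42. STL1 (HPODL_04540) of the hexose transport list differed by -1.37 in the wild type and 1.12 in the mutant, a difference of 2.49.

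Short genes were lower in both mutant libraries than in the wild-type libraries of the same medium. Many belong to the ribosome and the respiratory chain, but the 208 genes under 400 bases on no list had medians of -1.84 in B medium and -1.30 with cysteine, which argues against lower expression of those classes as the whole cause. The medians of the 9 length classes up to 1500 bases rose with length in both media. This is what a length-dependent step of library making or FPKM estimation that differed between the strains' libraries would give, and such a step may be part of the cause. A real effect of the strain on short transcripts was not tested and stays open.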

How the results depend on the processing

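The removal of the length trend, the limit to genes of at least 600 bases, the scaling to their total, the other list medians under scalings and named genes under TPM scaling were chosen after the data were seen. With no replicates, a count was called moved when it changed by more than 1.5 times and a log2 value when it moved by at least 0.58, and depth, which is unknown, limits every low value. With higher and lower genes summed, 48 counts of genes were within 1.5 times of the reported ones and 2 were not, both between the strains with cysteine, at 1596 with TPM scaling and 479 among genes of at least 600 bases, against 762 as deposited. With higher and lower genes apart, 89 counts of higher or of lower genes were within 1.5 times and 11 were not, 8 of these with TPM scaling, as between the strains in B medium (562 higher and 1332 lower, 2369 and 336 with TPM) and between the media in the wild type (1259 and 692, 753 and 1125 with TPM). The median of the sulfate assimilation list was -1.04 between the strains in B medium and 0.80 with cysteine under TPM scaling, against -2.24 and 0.04. These shifts follow from the division of each library by its own sum, since the sums differed (3217249 and 1407393 FPKM in B medium and 2314445 and 1329361 with cysteine, wild type first). The sums over genes of at least 600 bases were more even, at 920071 and 784743 FPKM in B medium and 871386 and 840525 with cysteine. Most of the unevenness behind the TPM shifts thus lay in shorter genes. Taking each list median once per alternative, 667 values moved by less than 0.58. A further 58 moved by more, 56 with TPM scaling and 2 with the length trend removed. With median-of-ratios, upper-quartile and 600-base scaling no value could reach that limit. These scalings shifted the medians of all genes by at most 0.30. Their 140 values each, all within 0.58, therefore say nothing about stability. Of the values of list medians 92 changed sign, 38 of them with TPM scaling, all of them under 2-fold as deposited. Of the values of named genes, 4073 moved by less than 0.58, 461 by more and 2 that were at least 2-fold as deposited changed sign. Among them, the 756 values each under median-of-ratios and upper-quartile scaling could not reach that limit, for the same reason. In B medium between the strains, sti35 (HPODL_03615) went from -1.16 to 0.030 with TPM scaling, and MAL61 (HPODL_05109) from -1.35 to 0.96 with the length trend removed, and the cause was not tested. These 2 leave out THI72 (HPODL_04535), which went from -1.16 to a value that rounds to 0 in the same comparison with TPM scaling, by a rule set after that value had been seen. Of the values of named genes under 2-fold as deposited, 80 of 1188 changed sign, 46 of them with TPM scaling, such as SKP1 in B medium between the strains (-0.81, 0.38 with TPM). The correlation of the 2 responses ranged from 0.488 to 0.515 over its 6 alternatives.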

Other observations

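All tests in this part were chosen after the results were seen. Genes at least 8-fold higher in wild-type B medium than with cysteine lay side by side in the genome more often than by chance placement. Among 166 such genes, 24 pairs were direct neighbours, where 10000 shuffles of gene order within chromosomes gave a median of 5, a 95th percentile of 10 and at most 17. The 3 longest runs of such neighbours lay at the right end of the annotated genes of chromosome II, where 14 of the 21 genes beyond position 950000, a boundary set after seeing the data, were at least 8-fold higher. The first of these runs begins before that boundary, with HPODL_05051 (949375 to 950799), and the last ends with SEO1 at HPODL_05071 (988960 to 990573). The stretch holds the sulfonate dioxygenase row HPODL_05052, dmoA (HPODL_05068), annotated as a dimethyl-sulfide monooxygenase (1267 and 11.4 FPKM in wild-type B medium and with cysteine), nahG (HPODL_05069), annotated as a salicylate hydroxylase (1539.5 and 40.1), the dioxygenase ANS (HPODL_05070, 1677 and 47.2) and a second SEO1 row (HPODL_05067, 338 and 3.51). In mutant B medium the last 4 of these had 27.9, 65.5, 65.0 and 32.8 FPKM. The cysteine synthase row HPODL_05065 in the same stretch went the other way, with 480.0 and 1206 FPKM in the wild type. A shared control of these neighbours is a hypothesis that the count of 24 fits, though repeated copies with shared reads could add to it.

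Copper uptake and delivery genes were lower in B medium than with cysteine in both strains. In a list of 12 genes written after the data were seen, which includes COX15, an oxidase assembly factor not known to carry copper, the median was -2.60 in the wild type and -2.62 in the mutant, with 10 of the 12 at least 2-fold lower in each strain (the others were CCS1 at -0.47 and CTR2 at -0.96 in the wild type, and CCS1 at 0.46 and ATX1 at -0.15 in the mutant), while 13 iron uptake genes had medians of -0.36 and 0.04. The list also holds COX11, COX19 and COX23, described as oxidase assembly factors, and SCO1, described as mitochondrial. Mitochondrial ribosomal protein genes were lower in B medium too (medians -1.12 in the wild type and -1.92 in the mutant). How much of the copper list median is shared with mitochondrial genes was not tested. A trend with gene length does not account for the lower copper list, since the trend over all genes lay between -0.22 and 0.36 for the 12 genes and the smaller median was -2.54 with it removed, and nor does a fault of a single library, since the 2 strains share no library here and the smaller median as deposited was -2.60. A candidate explanation is a lower supply of free copper in the medium with cysteine, which binds copper. SOD1 (HPODL_01412), a copper enzyme, was higher in B medium by 1.58 in the mutant and 2.12 in the wild type, but SOD2 (HPODL_02458), which carries manganese, was higher there by more (3.69 and 4.04), so these values do not single out copper and the explanation stays open.

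The mating-type row MATA1 at HPODL_04024 (chromosome V, 444647 to 445219) was listed at 0 in both wild-type libraries and had 36.97 and 38.4 FPKM in the mutant, and its neighbour HPODL_04023 had 0 and 0.434 FPKM in the wild type and 166 and 185 in the mutant. Reads moved over from the other MATA1 row (HPODL_04015) do not account for the MATA1 values, since that row lost at most 3.88% of the FPKM that MATA1 gained. MATALPHA2 (HPODL_05244) had 434 and 589.6 FPKM in the wild type and 371 and 524 in the mutant. As deposited this is a loss, in FPKM times length, of up to 62.9% of what MATA1 and HPODL_04023 gained together, but its log2 differences of -0.22 and -0.17 are near the medians of all genes (-0.27 and -0.10), and they were 0.03 and -0.06 with median-of-ratios and 0.96 and 0.63 with TPM scaling. Whether its reads fall on those rows therefore cannot be told, and no sequence was used. An exchange of the strain labels as a whole does not account for the pattern, if Met4 activates sulfate assimilation here as in budding yeast, since in B medium 7 of 10 genes of that list were at least 2-fold lower and 0 higher in the libraries labelled mutant, and the median, -2.24 as deposited, was at most -1.04 under the 4 scalings. With cysteine, zip1 and HPODL_05198 had 202 and 2757 FPKM in the library labelled wild type and 0 in that labelled mutant. In B medium they had 485 and 2343 FPKM against 0. If zip1, chosen after its values were seen, is the deleted gene, this argues against an exchange of the labels with cysteine alone. The 0 values also argue against a sizeable share of cells that express this locus in the mutant cultures. Cells of another strain that do not express it were not tested and stay open. A difference at this locus between the strains other than the deletion cannot be told apart from an effect of the deletion, because only 1 mutant strain was compared.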
